A study of Mus musculus with 6 samples.

How the data were processed

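Messenger RNA of mouse cells was sequenced in 6 libraries. The SSC libraries (3) come from spermatogonial stem cells, the germline stem cells of the testis, taken from 6-day-old males. These cells were grown on STO fibroblast feeders with 10% serum, GDNF at 20 ng/mL, bFGF at 10 ng/mL, LIF and EGF. The iNSC libraries (3) come from neural stem cell-like cells obtained from such cells by transdifferentiation for 6 days. Per the labels' protocols, the cells were plated on laminin, given retinoic acid at 1 µM for 24 h, and then held in a medium with N2, B27, bFGF at 20 ng/mL, 1% serum and SB431542 at 10 µM, an inhibitor of the TGF-beta type I receptors ALK4, ALK5 and ALK7. Libraries were made with a stranded kit for polyadenylated RNA, per the labels. Groups and replicate numbers were taken from the sample titles, with which the source name and the stage label go together. A further label, the cell type, names the opposite group in all 6 samples and was not used. All 20 genes listed for germ cell identity had higher levels in the libraries titled SSCs, which argues for the titles.

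The authors deposited a single table with whole-number read counts and FPKM values for 55401 Ensembl genes in each library. FPKM is the count divided by the exonic length and by the column total. Recomputing it from the deposited counts, the exonic lengths of the table and the column totals gave the deposited FPKM for 100% of the values in every library, within 0.0051 FPKM. Neither the deposited counts nor the FPKM values carry any further normalization. HISAT2, DESeq2 and the mm9 genome are named in the submitters' processing notes, without versions or settings. The counting tool, and whether it used the strand, are not given in the sources used here. The gene coordinates of the table were compared with the GENCODE M21 annotation of GRCm38: 55141 identifiers were found there, and 54821 of them had identical chromosome, start and end. Coordinates are therefore given as the table has them, on GRCm38. Without knowledge of the strand setting, counts of antisense genes are uncertain. How reads that match several places were counted is not given either, so genes that share reads with paralogs or pseudogenes are also uncertain. Tex19.1 and Cst12 have close paralogs. Gapdh, at 2.57 ± 0.641 FPKM in SSCs and 3.22 ± 0.0794 FPKM in iNSCs, has many pseudogenes.

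The plan written before the data were examined assumed FPKM values alone and set limma on log2(FPKM + 1) as the test, with edgeR in its place if raw counts were found. Since the table holds counts, edgeR 4.0.16 under R 4.3.3 was used, with TMM scaling, its default expression filter (a minimum count of 10 and a total of 15) and the quasi-likelihood test, two-sided. A gene was called higher or lower in iNSCs at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, and "rose" and "fell" are used in that sense. All log2 differences are iNSCs minus SSCs. Means ± SD are of FPKM over the 3 libraries of a group. FPKM ratios differ slightly from the TMM-scaled differences: with library totals in place of TMM, log2 differences moved by a median of -0.25. Where a group had 0 counts, a bound was computed against 3 counts over the group. With 1 to 3 counts, the ratio of scaled counts is given with its 95% Clopper-Pearson interval. Both cover counting error only.

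Before the data were examined, 25 gene lists were fixed and the genes named in the text were set by a rule. The rule took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, that had a mean of at least 10 FPKM in the higher group and that had an ordinary symbol. It added up to 2 called members of each list with the largest change and a fixed set of 23 genes around YTHDF1, NF-kB, cyclin D1, spermatogonia and neural stem cells. It was written for limma differences and applied to edgeR's. Other members are named where they make up a count of 5 or fewer, or in the closing section, after their values were seen. Some genes that these rules would name are not reported here. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. The direction of a list under other settings was read from the sign of its median, a choice made after the data were examined.

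Total counts were 19370976, 18058551 and 18718441 in SSCs replicates 1 to 3 and 18761528, 19527726 and 20156067 in iNSCs replicates 1 to 3. At this depth 3 counts in a library correspond to 0.149 to 0.166 CPM, that is counts scaled to a common library total. The labels do not say that the replicates are separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 4.97 to 8.93 among iNSCs and 35.3 to 91.5 among SSCs over genes with at least 20 counts, and each library was counted as a separate sample. The biological coefficient of variation was 30.8% among SSCs and 7.46% among iNSCs, while the test assumes a common spread. On simulated counts for 17042 tested genes, edgeR recovered 58% of genes changed 2-fold and 99% of those changed 4-fold, with 5 false calls. The simulation changed 200 genes, used a dispersion of 0.05 in both groups and counted calls by adjusted p alone. It therefore does not measure recovery under the size threshold, the unequal spread or the many changes of these data.

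In all, 23 other settings were tried: other filters, scalings, tools (DESeq2 1.42.0 and limma), size thresholds, a replicate block, an estimated correlation, each library left out in turn, and SSCs replicate 3 alone against iNSCs, the last chosen after seeing the data. In that last setting the lone SSC library is taken to vary as the iNSCs do. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.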

Results

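The transcriptomes of cultured spermatogonial stem cells (SSCs) and of the neural stem cell-like cells (iNSCs) derived from them were compared, with 3 libraries each and 18058551 to 20156067 counts per library. The study asks how the m6A reader YTHDF1 and the path from IkB and NF-kB to cyclin D1 relate to this change of fate. The groups also differ in feeders or laminin, serum, growth factors, retinoic acid and SB431542. Differences due to fate, to the media and to other cells in the cultures therefore cannot be told apart in these libraries. The groups separated on the first principal component, which held 91.0% of the variance. The second (4.85%) set SSCs replicate 3 (-60.9) apart from SSCs replicates 1 (49.5) and 2 (17.1). Correlations of log2 CPM across genes were 0.991 among iNSC libraries, 0.953 to 0.977 among SSC libraries and 0.702 to 0.754 between groups.

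Of 17387 genes tested, 4470 rose and 4797 fell in iNSCs (edgeR quasi-likelihood test). At least 8-fold changes were seen for 1234 genes upward and 1753 downward. Upward calls made up 48.2% of the total, and 39.6% with library totals in place of TMM. Among the largest rises were Cdh16, a cadherin of kidney tubule epithelium, from 0.0900 ± 0.0265 to 127 ± 9.32 FPKM (log2 10.70, SE 0.20), and, from 0 counts in SSCs, the collectin Sftpd (at least 544-fold higher), the matrix protease Mmp7 (at least 384-fold), Spaca7 (at least 317-fold) and the antisense gene Slc13a2os (at least 892-fold), whose reads cannot be told from those of its partner without strand. With 1 to 3 counts in SSCs, scaled counts of Mab21l4 were 2559 times higher (95% interval 459 to 101130), those of Il1f6, an interleukin 1 family cytokine, 2018 times (558 to 16665) and those of Tmem171 1924 times (658 to 9334). Their log2 differences rest on where those few counts lie: Mab21l4 went from 10.83 to 12.62 without SSCs replicate 3, and without SSCs replicate 1 Il1f6 was at 13.25 and Tmem171 at 13.77, against 10.715 and 10.73 with it. The largest falls included the neuropeptide gene Cartpt (1358 counts against 1, a ratio of 1183, 212 to 46774), Igsf21 (1140 counts against 1, a ratio of 993, 178 to 39270), at log2 -11.74 without iNSCs replicate 3 and -11.50 without iNSCs replicate 1, against -9.79 and -9.54 with them, and the transcription factors Zic1 (log2 -9.04, SE 0.54) and Egr4 (log2 -8.38, SE 0.34). Car6, a secreted carbonic anhydrase, fell from 15.7 ± 2.95 to 0.0633 ± 0.0416 FPKM.

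The first comparison concerns the germ cell state. Most of the listed genes of spermatogonia, of germ cells in general and of meiosis fell in iNSCs. Gfra1, the GDNF co-receptor of spermatogonial stem cells (ENSMUSG00000025089, chromosome 19, 58235604 to 58455909, minus strand), went from 40.0 ± 16.5 to 0.123 ± 0.0379 FPKM (log2 -8.07, SE 0.46, adjusted p = 7.8e-06). Zbtb16, a transcription factor of stem cell maintenance, fell by 6.83 on the log2 scale, and Nanos2, an RNA-binding protein of the same cells, was at least 148-fold lower, with 509 counts in SSCs and 0 in iNSCs. Ddx4, the germ cell RNA helicase, went from 142 ± 6.74 to 1.40 ± 0.159 FPKM and Dazl, an RNA-binding protein, from 225 ± 20.1 to 6.82 ± 1.39 FPKM.

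Of 24 tested genes for undifferentiated spermatogonia, 19 fell and 2 rose, also when adjusted over the list alone (median -5.42, camera adjusted p = 1.4e-07, and adjusted p = 0.334 with an estimated correlation). The fallers include the GDNF receptor Ret (log2 -2.33), the transcriptional regulator Id4 (log2 -2.54), Pax7 (at least 76.4-fold lower) and Etv5, a GDNF-responsive factor (log2 -1.34). Without SSCs replicate 3 the differences were -0.91 for Etv5 and -1.82 for Id4. The risers, Cdh1 and Tspan8, encode an epithelial cadherin and a tetraspanin. All 20 germ cell identity genes fell, also when adjusted over the list alone (median -5.51, adjusted p = 1.2e-32, and adjusted p = 0.0802 with an estimated correlation), led by Rhox10 (log2 -7.38, and -8.57 without iNSCs replicate 3) and Tex19.1 (log2 -6.82). Of 18 genes for spermatogonial differentiation and meiosis, 16 fell and 0 rose, also when adjusted over the list alone (median -3.54, adjusted p = 2.3e-08, and adjusted p = 0.163 with an estimated correlation), among them the spermatogonial factor Sohlh1 (log2 -5.93) and the synaptonemal complex gene Syce1 (log2 -4.43). Of 12 pluripotency genes, 9 fell and 1 rose, also when adjusted over the list alone (median -5.08, adjusted p = 2.7e-05, and adjusted p = 0.163 with an estimated correlation). Pou5f1 fell from 27.4 ± 2.71 to 0.0833 ± 0.0115 FPKM and Dppa2 was at least 69.7-fold lower, while Tfcp2l1 rose by a log2 difference of 2.94. Without SSCs replicate 3, 2 pluripotency genes rose.

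**Figure D1:**
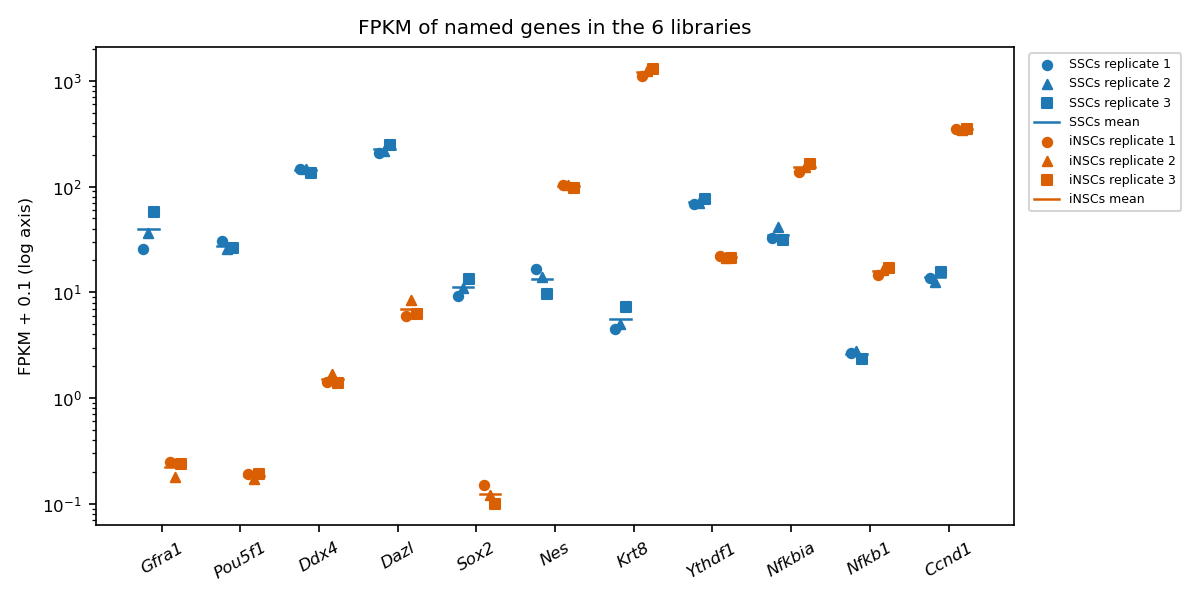
FPKM plus 0.1 on a log axis for 11 named genes, with SSCs in blue and iNSCs in orange, a symbol for each replicate and a line at the mean of 3 libraries. Krt8 had a mean of 5.51 FPKM in SSCs and 1217 in iNSCs, and Sox2 11.1 and 0.0233.

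The next comparison asks which neural transcripts the iNSCs carried. The neural stem cell list split: 7 of its 16 tested members rose and 8 fell, also when adjusted over the list alone (median -0.90, camera adjusted p = 0.939). The intermediate filament gene Nes (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451, plus strand) rose from 13.3 ± 3.48 to 101 ± 4.37 FPKM (log2 3.19, SE 0.19, adjusted p = 8.8e-06). Prom1, a membrane glycoprotein also known as CD133, rose by a log2 difference of 9.16, and the transcription factor Sox9 from 3.56 ± 0.704 to 21.9 ± 1.67 FPKM. Sox2, a transcription factor of neural and pluripotent stem cells (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461, plus strand), fell from 11.1 ± 2.03 to 0.0233 ± 0.0252 FPKM, that is 1282 counts against 3, a ratio of 372 (127 to 1808), and its log2 difference of -8.39 was -9.24 without iNSCs replicate 1. Nr2e1, a nuclear receptor of neural progenitors, had 267 counts in SSCs and 0 in iNSCs, at least 77.6-fold lower.

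Pax6, a regulator of neural progenitors, was near the floor in both groups, at 0.0867 ± 0.0351 and 0.0333 ± 0.0115 FPKM (log2 -1.31, adjusted p = 0.0441, with a range of 0.0191 to 0.157 over all settings). Fabp7 (1 and 23 counts in all) and Gfap (17 and 17 counts) of radial glia and astrocytes were too low to be tested. Of 15 neuronal genes, 3 rose and 9 fell, also when adjusted over the list alone (median -2.58, camera adjusted p = 0.477). Without SSCs replicate 3 the counts were 5 and 9 of 16 (median -1.66), and without SSCs replicate 2 they were 4 and 9 (median -1.96). The tubulin gene Tubb3 rose from 10.4 ± 6.48 to 68.8 ± 6.05 FPKM (SE of the log2 difference 0.38, and a difference of 3.59 without SSCs replicate 1), and the other risers were Gap43 (log2 2.75) and Stmn2, at 0.513 ± 0.251 FPKM in iNSCs (167 counts against 2, a ratio of 95.8, 26.1 to 798, with a log2 difference of 6.32, or 8.90 without SSCs replicate 3). Rbfox3, the neuronal nuclear antigen NeuN, fell from 232 counts to 2, a ratio of 101 (27.7 to 840), with a log2 difference of -6.42, or -9.19 without iNSCs replicate 1. Of 9 glial genes, 4 rose (Mbp, Aldh1l1, Slc1a2 and Aqp4) and 2 fell (Sox10 and Cspg4), also when adjusted over the list alone (median 0.41, adjusted p = 0.383). The glial median was 1.13 without SSCs replicate 1 and 1.04 without iNSCs replicate 3, and 1 gene fell without iNSCs replicate 1. The water channel Aqp4 was at least 37.1-fold higher, yet at 0.550, 0.150 and 0.120 FPKM in iNSCs replicates 1, 2 and 3 (log2 8.14, and 7.19 without iNSCs replicate 1), and Sox10, a factor of oligodendrocytes, was at least 59.5-fold lower. For the neural stem cell list the median and the mean (-0.89) were negative while camera's direction was upward, and its median was 2.22 when only genes of at least 5 FPKM in 3 libraries were kept.

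**Figure D2:**
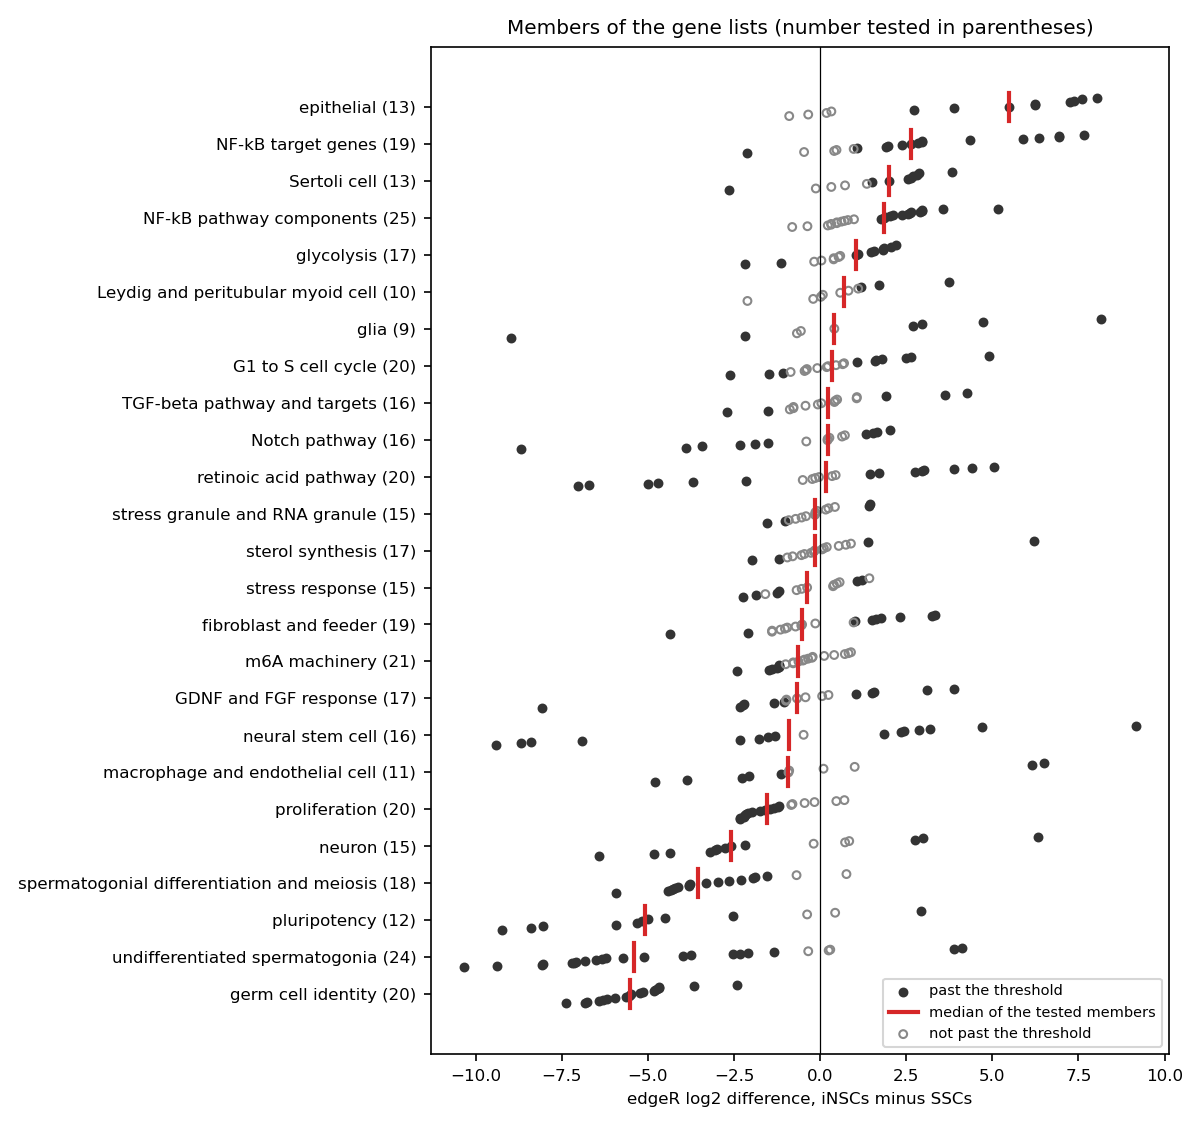
Log2 difference (edgeR, iNSCs minus SSCs) of each tested member of the 25 lists, filled where past the threshold, with a red bar at the list's median. Medians run from -5.51 for germ cell identity to 5.49 for epithelial genes.

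Markers of other cell types were measured in the same libraries. Epithelial genes held the highest median of all lists: 9 of 13 rose and 0 fell, also when adjusted over the list alone (median 5.49, camera adjusted p = 1.6e-11, and adjusted p = 0.287 with an estimated correlation). Krt8, a keratin of simple epithelia (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482, minus strand), rose from 5.51 ± 1.48 to 1217 ± 93.7 FPKM (log2 8.03, SE 0.29, adjusted p = 1.8e-06), and Cldn6, a tight junction protein, from 1.09 ± 0.271 to 177 ± 8.53 FPKM. Of 13 Sertoli cell genes, 8 rose and 1 (Rhox5) fell, also when adjusted over the list alone (median 2.00, adjusted p = 0.125), led by the cystatin gene Cst12 (log2 3.83, and 5.60 without SSCs replicate 1) and by Sox9. SSCs replicate 1 stood apart here: Cst12 had 9.69, 0.340 and 1.88 FPKM in SSCs replicates 1, 2 and 3, and Clu, a secreted chaperone chosen after its values were seen, 280, 44.2 and 94.97 FPKM. The Sertoli list passed the threshold under limma on log2(FPKM + 1), the test first planned (adjusted p = 0.00766), and without SSCs replicate 1 (adjusted p = 5.2e-04), with a range of 5.2e-04 to 0.205 over the settings at the preset correlation, and adjusted p = 0.770 with an estimated correlation. Its median was 2.83 without SSCs replicate 1, and 2 members fell without SSCs replicate 2 and 0 without iNSCs replicate 3. Of 11 macrophage and endothelial genes, 2 rose, the receptor Csf1r (log2 6.16, and 7.04 without SSCs replicate 1) and the lipopolysaccharide co-receptor Cd14 (1.27 ± 0.296 to 96.3 ± 14.6 FPKM), and 5 fell (Tek, Pecam1, Vwf, Tie1 and Kdr), or 2 and 4 when adjusted over the list alone (median -0.92, adjusted p = 0.974). Fallers numbered 3 without SSCs replicate 2, iNSCs replicate 1 or iNSCs replicate 2, and 1 epithelial gene fell without SSCs replicate 1 or with library totals in place of TMM. Other macrophage genes, chosen after their values were seen, were near the floor in iNSCs, such as Ptprc (0.187 FPKM), Adgre1 (0.147 FPKM) and C1qa (0 FPKM). Cd68 (8.10 FPKM) and Lyz2 (5.59 FPKM) were above it in iNSCs but were not called.

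SSCs replicates differed in fibroblast and smooth muscle transcripts. Col1a1, the main collagen of fibroblasts, had 189, 168 and 23.0 FPKM in SSCs replicates 1, 2 and 3 and 34.4, 33.1 and 51.4 FPKM in the iNSC libraries, and the smooth muscle actin Acta2 had 367, 310 and 16.2 FPKM against 213, 185 and 204 FPKM. These genes were chosen after their values were seen. Of 19 fibroblast and feeder genes, 7 rose and 2 (Postn and Lox) fell, also when adjusted over the list alone (median -0.52, mean 0.08, camera adjusted p = 0.668). Dcn, a matrix proteoglycan, rose by a log2 difference of 3.33 (4.10 without SSCs replicate 3), and Postn, a matrix protein, fell by 4.36 on the log2 scale, with 12.3, 9.67 and 0.490 FPKM in SSCs replicates 1, 2 and 3. Against SSCs replicate 3 alone the log2 difference of Postn was -0.50, under the size threshold. That library was picked for its low fibroblast transcripts, so this is no separate evidence on Postn. Without SSCs replicate 3 the counts were 6 risers and 10 fallers (median -1.03), without SSCs replicate 2 the median was 0.11, and without iNSCs replicate 3 there was 1 faller. Of 10 Leydig and myoid genes, 3 rose (Hsd3b1, Nr5a1 and Cyp11a1) and 0 fell, also when adjusted over the list alone (median 0.70, adjusted p = 0.524), with 1 riser without SSCs replicate 2, and 2 risers and 1 faller without SSCs replicate 3. The steroid dehydrogenase Hsd3b1 had a log2 difference of 3.73 (4.71 without SSCs replicate 1) and the steroidogenic factor Nr5a1 of 1.71 (2.56 without SSCs replicate 1, adjusted p = 0.0182, with a range up to 0.0715 over all settings).

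**Figure D3:**
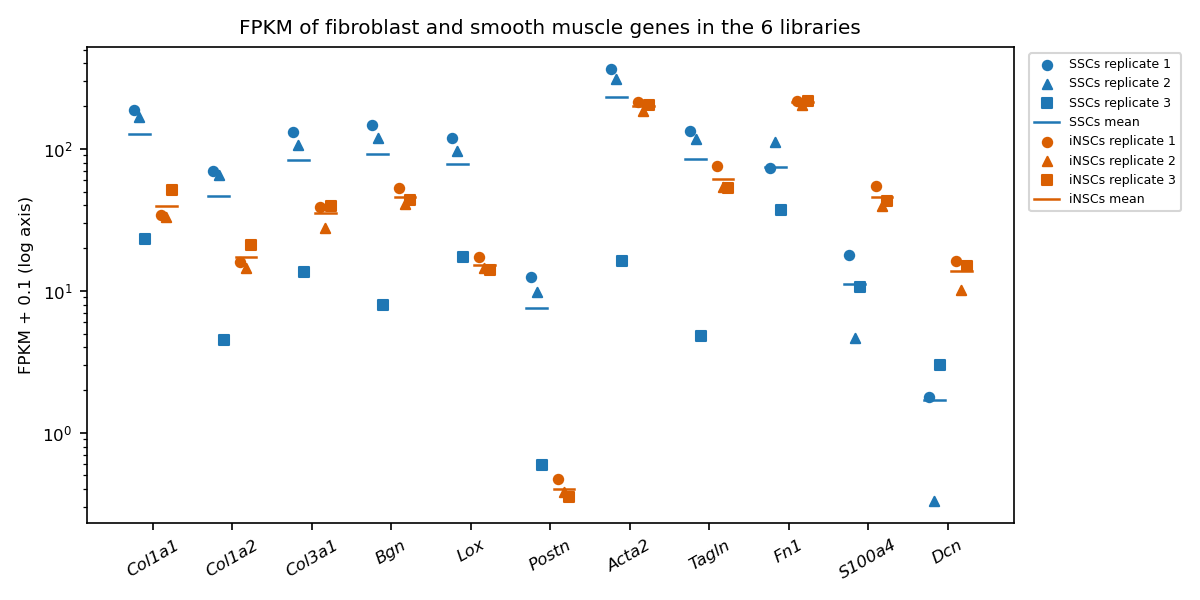
FPKM plus 0.1 on a log axis for 11 fibroblast and smooth muscle genes, chosen after their values were seen, with a symbol for each replicate and a line at the mean of 3 libraries. Bgn had 147, 119 and 7.87 FPKM in SSCs replicates 1, 2 and 3.

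The study's title places YTHDF1 upstream of NF-kB and cyclin D1. The labels name no library in which YTHDF1 was perturbed, and mRNA levels do not measure m6A, protein or NF-kB activity. The values below therefore cannot test that order. Ythdf1 mRNA (ENSMUSG00000038848, chromosome 2, 180904377 to 180920949, minus strand) was lower in iNSCs, at 21.4 ± 0.670 FPKM against 71.5 ± 3.57 FPKM (log2 -1.49, SE 0.11, adjusted p = 1.9e-05). Mettl3, the catalytic subunit of the m6A methyltransferase, went from 12.8 ± 1.44 to 4.73 ± 0.340 FPKM (log2 -1.19, SE 0.15). Of 21 genes of the m6A machinery, 7 fell and 0 rose, also when adjusted over the list alone (median -0.63, camera adjusted p = 0.182). Without SSCs replicate 3, 6 fell and 2 rose. The m6A-binding protein gene Igf2bp1 fell most (log2 -2.40). The list passed the threshold under limma on log2(FPKM + 1), the test first planned (adjusted p = 0.0365), with a range of 0.00377 to 0.266 over the settings at the preset correlation, and adjusted p = 0.948 with an estimated correlation.

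Several NF-kB genes rose. Nfkbia, which encodes the inhibitor IkB alpha and is itself induced by NF-kB (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647, minus strand), rose from a mean of 34.9 to a mean of 152 FPKM (log2 2.38, SE 0.15, adjusted p = 1.1e-05), and Nfkb1, the p50 precursor, from 2.51 ± 0.235 to 15.8 ± 1.18 FPKM (log2 2.91, SE 0.12). Rela, the p65 subunit, and Nfkbib, another inhibitor, were not past the size threshold (log2 0.80 and 0.71, adjusted p = 2.6e-04 and 0.00135). Of 25 pathway components, 14 rose and 0 fell, also when adjusted over the list alone (median 1.86, camera adjusted p = 3.6e-06, and adjusted p = 0.107 with an estimated correlation), with the kinase Ikbke (log2 5.15) and the inhibitor Nfkbie (log2 3.58) at the top. Of 19 NF-kB target genes, 14 rose and 1 (Mmp9) fell, also when adjusted over the list alone (median 2.63, adjusted p = 3.7e-06, and adjusted p = 0.163 with an estimated correlation). Lcn2, a secreted siderophore-binding protein, rose from 11.1 ± 9.73 to 1878 ± 156 FPKM, and the cytokine gene Tnf by a log2 difference of 6.95. Without SSCs replicate 1 the log2 difference of Lcn2 was 8.52, against 7.68 with it, and that of Tnf 7.80. Nfkbia and Tnfaip3 belong to both lists. Without SSCs replicate 1, or with library totals in place of TMM, 1 pathway component fell.

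Ccnd1, the gene of cyclin D1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand), rose from 13.8 ± 1.51 to 348 ± 3.34 FPKM (log2 4.91, SE 0.15, adjusted p = 1.2e-06). Of 20 genes of the G1 to S transition, 7 rose and 3 (Cdkn1c, E2f1 and Cdk2) fell, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.477). Cdkn2c, an inhibitor of CDK4 and CDK6, rose by a log2 difference of 2.64. Of the proliferation genes, 14 of 20 fell and 0 rose, also when adjusted over the list alone (median -1.54, adjusted p = 2.7e-05, and adjusted p = 0.736 with an estimated correlation). The replication helicase gene Mcm2 went from 91.1 ± 10.9 to 15.4 ± 0.959 FPKM and the mitotic checkpoint kinase gene Bub1 from 30.8 ± 3.72 to 5.16 ± 0.254 FPKM.

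The remaining lists follow the signals in the media. Of 20 retinoic acid genes, 8 rose and 6 fell (median 0.16, mean -0.21, camera adjusted p = 0.492). The receptor gene Rxrg (197 counts against 1, a ratio of 172, 30.5 to 6814) and Hoxb1 (164 counts against 1, a ratio of 143, 25.3 to 5679) had the largest falls. The log2 difference of Rxrg was -7.02, or -6.32 without SSCs replicate 3 and -8.97 without iNSCs replicate 3, and that of Hoxb1 -6.72, or -8.67 without iNSCs replicate 3. Risers, chosen after their values were seen, include the retinol transporter gene Stra6 (log2 5.06, with 0.750, 0.100 and 0.150 FPKM in SSCs replicates 1, 2 and 3), the receptor Rarb (log2 4.40) and the retinaldehyde reductase Dhrs3 (log2 3.90). Of 16 TGF-beta genes, 3 rose, the receptor Tgfbr2 (4.42 ± 0.265 to 71.0 ± 5.04 FPKM), the ligand Tgfb2 (log2 3.62) and Smad3 (log2 1.92), and Pmepa1 and Skil fell (median 0.23, adjusted p = 0.477). Without SSCs replicate 3, 5 TGF-beta genes fell (median -0.0473), and 4 with library totals in place of TMM. Of 16 Notch genes, 4 rose (Notch3, Jag1, Lfng and Dll1) and 6 fell (median 0.22, mean -0.85, adjusted p = 0.974). The Notch effectors Hes5 (at least 48.5-fold lower) and Hey1 (log2 -3.89) were among the fallers. Of 17 genes of the GDNF and FGF response, 5 rose (Spry2, Spry1, Dusp4, Fgfr2 and Etv1) and 6 fell (median -0.67, or 0.0991 without SSCs replicate 3, adjusted p = 0.939). Etv1 had a log2 difference of 3.89 (4.62 without SSCs replicate 1) at 0.270 FPKM in iNSCs, and Gfra1 led the falls. These counts stayed the same when adjusted over the list alone.

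The last lists cover metabolism and stress. Of 17 glycolysis genes, 9 rose and 2 (Pdk1 and Aldoc) fell (median 1.05, camera adjusted p = 0.147), with 1 faller without iNSCs replicate 2. The glucose transporter Slc2a1 rose from 37.2 ± 3.53 to 144 ± 5.29 FPKM and Pdk1, an inhibitor of pyruvate dehydrogenase, fell by 2.17 on the log2 scale. Of 17 sterol genes, 2 rose and 2 (Insig1 and Dhcr7) fell (median -0.16, mean 0.21, adjusted p = 0.792), with 4 risers without SSCs replicate 3 (median 0.15) and 4 fallers with library totals in place of TMM. Insig1, a brake on sterol synthesis, had a log2 difference of -1.98. Of 15 stress granule and RNA granule genes, Usp10 and Tia1 (log2 1.44) rose and Edc4 (log2 -1.53) and Tial1 fell (median -0.14, adjusted p = 0.939), with 1 faller without SSCs replicate 3 or any single iNSC library. Tia1 was under the size threshold with limma on log2(FPKM + 1) (0.76). Of 15 stress response genes, Hmox1 and Gadd45a rose and Fos, Nupr1, Hspa1a and Trib3 fell (median -0.38, adjusted p = 0.974), or 1 rose without SSCs replicate 1, SSCs replicate 2 or iNSCs replicate 1, and 0 rose and 5 fell with library totals in place of TMM, with log2 differences of -2.24 for the immediate early gene Fos and -1.86 for Nupr1. Without SSCs replicate 1 the difference of Nupr1 was -1.03, and without iNSCs replicate 2 it missed the threshold (adjusted p = 0.0506, the highest over all settings, with a lowest of 5.3e-05). These counts stayed the same when adjusted over the list alone. Of the 25 lists, 8 were called by camera at the preset correlation, 3 upward and 5 downward. With an estimated correlation 0 were called, and 5 had an unadjusted p under 0.05.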

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

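The tests on SSCs replicate 3 alone were chosen after the data were examined, and so were the splits of the libraries. Genes rising (4470) numbered 2353 with a filter of 5 FPKM in 3 libraries, 2738 under limma on log2(FPKM + 1), 2737 without its trend, 2770 with array weights and 2375 at a log2 difference of at least 2. Genes falling (4797) numbered 2293 with the 5 FPKM filter, 3143 on quantile-normalized values and 2684 at the larger size. The filter tests fewer genes and the larger size admits fewer; for the other settings the cause was not tested. Leaving out each library gave 4411 to 4839 risers, 4730 to 5189 fallers and 8 to 9 called lists. Called lists (8) numbered 14 with SSCs replicate 3 alone (a library picked for its low fibroblast transcripts and given the iNSC spread, so no evidence on those lists) and 0 with an estimated correlation (5 at an unadjusted p under 0.05, camera). Under limma on log2(FPKM + 1), the test first planned, 10 were called, with Sertoli (adjusted p = 0.00766, range 5.2e-04 to 0.205 at the preset correlation) and m6A (adjusted p = 0.0365, range 0.00377 to 0.266 at the preset correlation) added. A replicate block gave 4510 and 4661 genes. Deviations of same-numbered libraries from their group means had correlations of 0.0907, 0.0496 and -0.0150, and those of other pairs ran from -0.0959 to 0.0535. The iNSC libraries varied little (7.46%), so low correlations cannot exclude pairing. The numbers were not read as pairs in the main setting. Under the block the Sertoli list was called by camera (adjusted p = 0.0283, within its range above) and Pax6 was not called. No named gene changed direction. Some lists not called in the main setting had medians that changed sign. With the 5 FPKM filter, neural stem cell was at 2.22 and stress at 0.26. With any count, glia was at -0.15. Library totals gave retinoic acid -0.11, TGF-beta -0.0288 and Notch -0.0208. Array weights gave macrophage and endothelial 0.69 and TGF-beta -0.10, and limma on quantile-normalized values gave macrophage and endothelial 0.01845. SSCs replicate 3 alone gave fibroblast 2.18 and Notch -0.22. Leaving out single libraries gave medians of -1.03 to 0.11 for fibroblast, -0.0473 to 0.28 for TGF-beta, -0.0305 to 0.54 for Notch, -1.0045 to 0.10 for GDNF and FGF, -0.32 to 0.15 for sterol and -0.65 to 0.0501 for stress, and the cause was not tested. Of the splits of the 6 libraries into 3 and 3, 10 exist, too few for a share under 0.05: the real split gave 4470 and 4797 genes and the highest of the others 0 (edgeR), with at most 75 genes at an unadjusted p under 0.05. As large a count came from 1 split, the real one. Each other split mixes SSC and iNSC libraries, which moves their difference into the spread. Its low count was thus set by the design and is no evidence on chance. Depth limits genes near 3 counts per group, such as Sox2 in iNSCs.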

Other observations

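The tests on Gene Ontology terms, on epithelial tissues, on SSCs replicate 3, on germ cell transcripts and on Sertoli and epithelial cells were all chosen after the results were seen. Among 952 biological process terms given in the deposited table, camera called 87 upward and 39 downward at the preset correlation. With an estimated correlation 0 were called by camera, and 70 had an unadjusted p under 0.05. Inflammatory response genes had 69 risers and 20 fallers among 139 (adjusted p = 4.6e-05, and adjusted p = 0.520 with an estimated correlation). Glutathione metabolism genes had 27 and 2 among 38 (adjusted p = 1.3e-04, and adjusted p = 0.520 with an estimated correlation), and kidney development genes 36 and 7 among 68 (adjusted p = 0.00220, and adjusted p = 0.520 with an estimated correlation). Genes of ribosome biogenesis had 1 riser and 26 fallers among 48 (adjusted p = 7.2e-04, and adjusted p = 0.527 with an estimated correlation), and genes of RNA splicing 7 and 55 among 133 (adjusted p = 0.00151, and adjusted p = 0.638 with an estimated correlation).

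Lists of markers of epithelial tissues, written after the keratin and claudin values were seen, were read for genes that rose and reached 5 FPKM in iNSCs. They numbered 8 of 14 for rete testis, efferent duct and kidney tubule, 5 of 7 for mesothelium, 2 of 8 for airway and lung, 1 of 8 for gut and liver, 1 of 8 for trophoblast and yolk sac, 0 of 9 for epididymis and 0 of 8 for skin and bladder. Pax8, a factor of kidney and duct epithelium, went from 0.583 ± 0.142 to 27.2 ± 2.01 FPKM, and the keratin Krt7 from 0.357 ± 0.172 to 205 ± 18.7 FPKM. The mesothelial gene Msln rose from 5.44 ± 4.05 to 133 ± 6.99 FPKM. Fallers were Lhx1 and Wnt9b in the kidney and duct list and Bnc1 in the mesothelium list. Other lists held fallers too, such as Afp of gut and liver (14.8 to 0.227 FPKM) and Tfap2c of trophoblast (log2 -7.15).

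Of 13 epithelial genes 9 rose (adjusted p = 0.287 for the list with an estimated correlation), while Sox2 fell, Pax6 stayed near the floor, and Sox1 and Olig2 had 0 FPKM in the iNSC libraries. Sertoli cells with their neonatal transcripts would bring Amh, whose mean in iNSCs was 0.123 FPKM, with 0.0267 FPKM for Fshr. Both were near the floor in SSCs too (0.573 and 0 FPKM), where Clu had 140 FPKM, and 8 of 13 Sertoli genes rose, so such cells stay open as a source. Outgrowth of epithelial cells already present in the SSC cultures may also give the pattern: SSC libraries held the 9 called epithelial genes at a median of 1.57% of their iNSC level. The share ran from 0.453% for Krt8 to 18.2% for Rab25, not a common share, but germ cells also express some of these genes, so outgrowth and induction during the change of medium cannot be told apart here.

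SSCs replicate 3 held fewer fibroblast and smooth muscle transcripts than SSCs replicates 1 and 2: of 13 fibroblast and feeder genes with at least 10 FPKM in SSCs, 12 were lower there, with a median log2 difference of -2.66. A lower depth is argued against by its 18.7 M counts, above those of replicate 2. Fewer feeder or other mesenchymal cells could give this, and would leave germ cell genes a larger share. The germ cell identity list differed by a median log2 of 0.0321, within random lists of matched expression (percentile 20.6), and the meiosis list by -0.12 (percentile 5.74). TMM scaling takes out a rise shared by most genes, and random lists from the same libraries would share it. These values therefore cannot decide whether germ cell genes held a larger share. Undifferentiated spermatogonia (0.72), GDNF and FGF response (0.66), epithelial genes (0.56), sterol synthesis (0.96), m6A machinery (0.35) and proliferation (0.30) were higher there. So were stress granule and RNA granule genes (0.28), and these higher lists lay at percentiles of 97.9 to 100 of random lists. Leydig and myoid (-2.44), TGF-beta (-1.11), glia (-0.74), retinoic acid (-0.34) and glycolysis genes (-0.15) were lower there, at percentiles of 0 to 2.08. Germ cell lists thus moved apart, and fewer mesenchymal cells as a source stay open. The labels name no biological difference between these replicates, and none was tested.

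Germ cell transcripts were low in the iNSC libraries but mostly not at 0: a median of 2.00% of the SSC level was left for undifferentiated spermatogonia genes, 1.83% for germ cell identity and 7.31% for differentiation and meiosis, while Nanos2 and Pax7 had 0 counts. A remnant of unchanged SSC culture, with its cells in the same proportions, would as the only source leave a common share. Among members of at least 5 FPKM in SSCs and 20 counts in iNSCs, log2 differences of the 19 germ cell identity genes had an SD of 1.08 against a median SE of 0.21, with shares from 0.746% to 15.7%, and those of the 15 meiosis genes an SD of 1.33 against 0.22, with shares from 1.35% to 52.0%, which argues against that source alone. By permutation test among genes of at least 5 FPKM in SSCs, the median of germ cell identity minus that of meiosis was -1.71 (p = 6.7e-04, adjusted over 4 contrasts p = 0.00134), and that of the undifferentiated list minus meiosis -1.31 (p = 0.0995, adjusted p = 0.0995), or -1.88 over all members (p = 0.0358, adjusted p = 0.0477). The permutation moved genes between lists, so its p-values take genes as independent and measure the spread between listed genes, not between samples. These contrasts were tried before the spread of shares and had left the source open. The spread bears only on an unchanged remnant with its cells in the same proportions. Left open are such a remnant beside expression in the changed cells, and a remnant whose own expression had changed. A remnant of only some of the cells of the SSC culture, which could leave unequal shares, is left open too.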
